A study of Mus musculus with 4 samples.

How the data were processed

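The samples were 4 Affymetrix arrays of total RNA from flow-sorted cells of cultured mouse embryonic kidneys, 2 of GFP-high and 2 of GFP-negative cells. Per the labels' protocols, kidneys were digested with a trypsin replacement and DNase, RNA was isolated on columns, and it was labelled with biotin using the manufacturer's whole-transcript kit. The values used are the log2 expression values that the authors deposited in the series' value table. The scanner, background correction, probe set summary, normalization and scaling behind them are not given in the sources used here. From the values, 2 to the power of the deposited log2 value was a multiple of 0.1 (within 0.001) for 100% of entries, and the upper quartiles of the 4 arrays lay between 7.62 and 7.72, while whether the arrays had been scaled to each other is not given in the sources used here. The centring and direction need no assumption, since these are levels of single arrays. No column of values was left unused (0). Array data have no read depth, and the number of arrays limits the precision.

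Each array's group was taken from its description, which names the reporter fraction and a number 1 or 2. The titles carry kidney letters, A and B for GFP-high and B and D for GFP-negative. Number and letter do not match, because number 1 joins kidneys A and B and number 2 joins B and D, so the main comparison used no block. What a letter stands for is not given in the sources used here.

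Genes were named through the platform annotation given with the data. Of 35556 probe sets, 21218 named a single gene, 1881 several and 12457 were unnamed here. Of the single-gene probe sets 21185 matched a gene identifier of the mouse RefSeq table (GRCm38.p6), and 0 symbols needed an update. The table was used for names only. For 1386 genes with several probe sets, the probe set with the highest mean over the 4 arrays stood for the gene, which left 18820 genes. Of the 100 genes taken by the rule for named genes given below, 5 had a further single-gene probe set. Of these 5 probe sets 1 (Prom1) had the opposite sign, without passing. Those of Etv5 and Slc8a1 passed when all probe sets were tested, while those of Socs3 and Kif11 did not. Probe sets with no or several gene names stayed out of the gene test.

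Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all 18820 genes at a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 5.11. No filter on dim genes was set. SE is the moderated standard error of the log2 difference, GFP-high minus GFP-negative, and a fold is 2 to the power of its size. As a reference for background the 990 olfactory receptor genes were used, with a median log2 value of 3.32 and a 95th percentile of 4.24. This reference was chosen after the data were seen.

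Gene lists of kidney cell types, pathways and stress responses were written before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 27 lists, 1 held Lgr5 alone and 26 with at least 3 measured members were tested with camera of limma against all other genes, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26. Of 399 genes on the lists 362 were measured. Camera with an estimated correlation, which rests on the 2 residual degrees of freedom, and fry were run beside it. For each list the members that passed over all genes were counted, and those that passed when adjusted over the list alone.

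The rule for named genes took Lgr5, the 12 largest differences in each direction among genes with adjusted p below 0.05 and no overlap between groups (predicted and clone-like symbols left out), up to 4 passing members per list by size of the difference, or the 2 largest where none passed, and every sex-linked gene on the list. Further list members are given as examples of genes that passed or did not, and were chosen after their values were seen.

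The gene and list tests were checked on 20 sets of simulated arrays with the means of the 18820 genes, variances drawn from the distribution fitted to them and 200 changed genes each. For the comparison of GFP-high with GFP-negative, 1.29% of genes changed by 0.5 on the log2 scale were called in the right direction, 67.4% of those changed by 1 and 98.5% of those changed by 2, and 4.76% of calls were unchanged genes. In the data far more genes were called (3620), which loosens the threshold that adjustment sets. The shares of changed genes found therefore do not carry over to the data. Camera found 100% of simulated lists of 18 genes shifted by 0.5, and 2.3% of unshifted lists had an unadjusted p below 0.05, with genes simulated as independent.

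Alternatives were the array number as a block, the kidney letters as a crossed block, quantile, median and cyclic loess normalization, filters at the median and the 25th percentile of level, the mean of a gene's probe sets, all probe sets, eBayes with trend or robust variance, other thresholds, and leaving out each array in turn, where the lone array of a group is assumed to vary like the others. A fit without 1 array leaves 1 residual degree of freedom, so adjusted p rises even where the difference holds. Lgr5, for example, kept a log2 difference of 3.995 to 4.083. A lost call alone therefore does not show that a gene depends on the array left out. Level-matched random lists of genes used 1000 draws and bootstrap intervals over genes 10000. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.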

Results

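Metanephric kidneys of mouse embryos were dissected at about day 14 of gestation and kept in organ culture for about 10 days. The mice carried a reporter that places enhanced green fluorescent protein (EGFP) under the control of Lgr5, the gene of a Wnt-potentiating R-spondin receptor that marks stem cells in the intestine. Fluorescent kidneys were digested to single cells, and flow cytometry collected a fraction with high GFP and a fraction without it. Total RNA of each fraction was hybridised to Affymetrix expression arrays, with 2 arrays of GFP-high cells (kidneys A and B by their titles) and 2 of GFP-negative cells (kidneys B and D). The deposited values, on a log2 scale, had medians of 5.07 and 5.19 on the GFP-high arrays and 5.22 and 5.24 on the GFP-negative arrays, over 35556 probe sets. The number of arrays limits the precision of every value, and because the labels do not say whether the letters stand for separate animals or litters, p-values measure only the spread between these 4 arrays, which may be technical.

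The comparison asks which genes set the Lgr5-reporter cells of the cultured embryonic kidney apart from the cells without reporter. Lgr5 itself, which checks the sort, had a log2 value of 10.39 ± 0.062 in GFP-high cells and 6.35 ± 0.054 in GFP-negative cells (SD, n = 2 each), 16.4-fold higher (log2 difference 4.04, SE 0.122, limma adjusted p = 1.106e-05). Of 18820 genes tested, 1520 were higher and 2100 lower in GFP-high cells, and of the 3620 together 1651 differed at least 2-fold. Differences of at least 8-fold were more often decreases, with 142 genes lower and 29 higher. With each array centred on its median the split turned to 2122 higher and 1889 lower, since centring moved the median difference of all genes from 0.051 to 0.147. The counts fell to 1123 without the GFP-high array of kidney A, 1241 without that of kidney B, 1631 without the GFP-negative array of kidney B and 1749 without that of kidney D.

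The largest increase was that of Sim2, a bHLH-PAS transcription factor, which reached 11.08 ± 0.034 against 5.62 ± 0.24 in GFP-negative cells (SD, n = 2 each), a 44.2-fold difference. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, was 33.9-fold higher at 10.39 ± 0.023, and Umod, which encodes the uromodulin secreted by the same segment, was 32.7-fold higher at 10.28 ± 0.51. The homeobox genes Irx2 and Irx1 were 28.0-fold and 26.1-fold higher, and Tfap2b, an AP-2 transcription factor, was 27.3-fold higher. Stk32b (21.1-fold), the adhesion molecule gene Nrcam (21.0-fold), the cystine transporter gene Slc7a11 (16.9-fold), Fndc3c1 (13.5-fold) and Grhl2 (12.5-fold), a transcription factor of epithelia, completed the 12 largest increases together with Lgr5. Adjusted p was at most 3.551e-05 in these 12 genes. Nrcam in GFP-negative cells, at 4.16, lay below 4.24, the 95th percentile of olfactory receptor genes, which are taken here as a background level.

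The largest decrease was that of Six2, the transcription factor that keeps nephron progenitors undifferentiated, with a value of 5.40 ± 0.38 in GFP-high and 10.17 ± 0.078 in GFP-negative cells (SD, n = 2 each), 27.1-fold lower. Itga8, an integrin alpha subunit on progenitor and mesenchymal cells, was 23.7-fold lower, and Osr1, an early marker of the nephrogenic lineage, 18.3-fold lower. Slc34a1, the phosphate cotransporter of the proximal tubule, was 20.2-fold lower. Snai2 was 17.0-fold lower and Penk 16.6-fold lower, and Gucy1a1 (20.3-fold), Lix1l (19.4-fold), Sparcl1 (19.3-fold), Cped1 (18.9-fold), Cygb (18.3-fold) and Islr (17.2-fold) made up the rest. The highest adjusted p among these 12 genes was 5.994e-05, for Slc34a1.

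**Figure D1:**
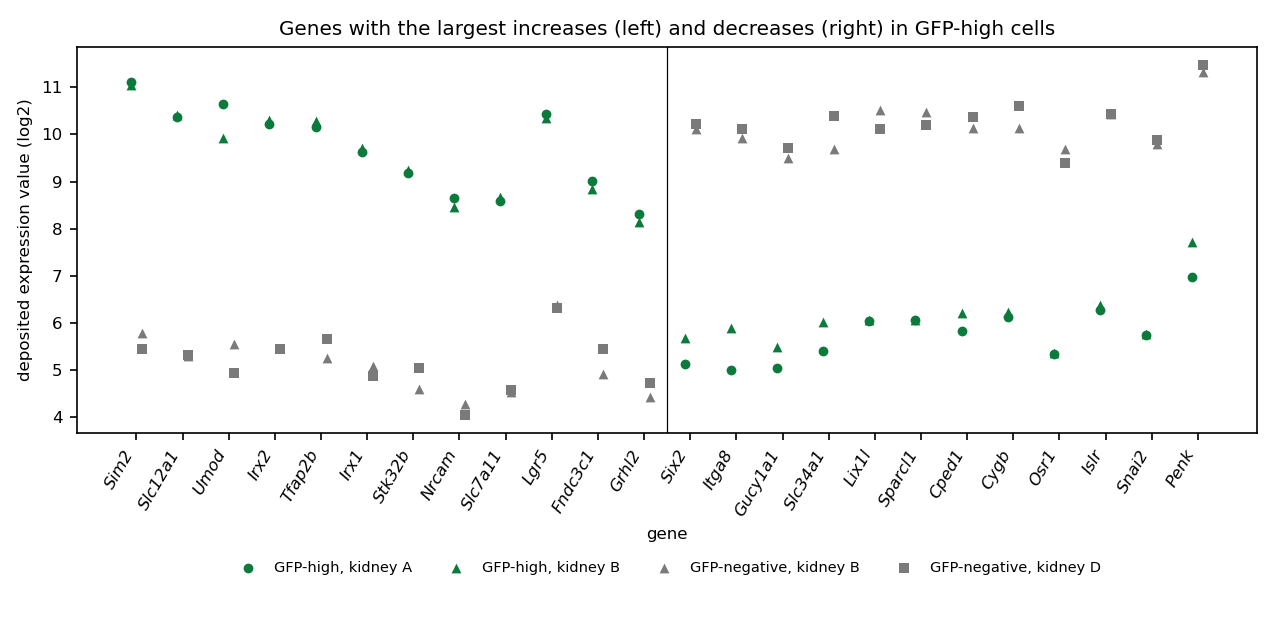
Deposited log2 expression value on the vertical axis of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right) in GFP-high cells, 1 symbol per array, green for GFP-high and grey for GFP-negative, with the symbol shape giving the kidney letter. For Lgr5 the GFP-high arrays sit at 10.43 and 10.34 and the GFP-negative arrays at 6.38 and 6.31, and in no plotted gene do the groups overlap.

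Genes of the thick ascending limb were raised as a group in GFP-high cells, with 11 of 16 measured members higher, 0 lower and 5 not passing (12 higher when adjusted over the list alone). Of the 11, 10 passed without each of the 4 arrays in turn. Beside Slc12a1 and Umod these included Cldn19 at 9.14 against 5.55, Cldn16 at 6.91 against 4.08, both claudins of the paracellular cation route of this segment, and the potassium channel gene Kcnj1 at 7.38 against 4.31. Egf, at 4.51 in both groups, and Ptger3, at 4.66 against 4.53, did not pass. The list's median log2 difference was 2.73, and its shift against all other genes had adjusted p = 4.92e-12 with the preset correlation of camera (adjusted p = 0.266 with an estimated correlation). The list shares Irx1 and Irx2 with that of the S-shaped body. In the latter, 9 of 18 members were higher, 4 lower and 5 not passing (10 higher and 4 lower when adjusted over the list alone). The higher ones were Sim2, Irx1, Irx2, Tfap2b, Sim1, Mecom, Pou3f3, Sox9 and Ehf, and the lower ones Osr2, Npy, Wnt4 and Cxcl12. All 9 passed without each array in turn, but Wnt4 did not without the GFP-high array of kidney A (adjusted p = 0.0568), and Cxcl12 did not with any 1 of the 4 left out (adjusted p 0.0754 to 0.184). Sim1 stood at 10.42 against 6.83 and Pou3f3, a regulator of distal tubule formation, at 9.32 against 5.83, while Osr2 stood at 7.47 against 10.63. The S-shaped body list had adjusted p = 0.00132 for an upward shift (adjusted p = 0.407 with an estimated correlation).

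Of 15 genes of the distal convoluted and connecting tubule, 5 were higher, 1 lower and 9 did not pass (7 higher and 2 lower when adjusted over the list alone). Of the 5 higher, 2 passed without each array in turn. Sall3, a zinc finger transcription factor, was 7.37-fold higher from a GFP-negative value of 3.80, below the background level of 4.24, and Tmem52b was 5.48-fold higher. Slc8a1, a sodium-calcium exchanger gene, was 3.21-fold lower. Slc12a3, the sodium-chloride cotransporter that defines the distal convoluted tubule, was at 4.99 against 5.32 and did not pass. Gata3 was 2.43-fold higher, with adjusted p = 0.0226 without the GFP-high array of kidney B but 0.075 without that of kidney A, where its log2 difference fell from 1.28 to 0.787, and 0.2 and 0.235 without the GFP-negative arrays of kidneys B and D, and with 0.0693 when all probe sets were tested. The list did not pass (adjusted p = 0.11), although it did without the GFP-negative array of kidney D (adjusted p = 0.0358) and with genes below the median level left out (adjusted p = 0.0263).

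General epithelial genes were higher almost throughout, with 16 of 18 members higher, 0 lower and 2 not passing (16 higher when adjusted over the list alone). Of the 16, 8 passed without each array in turn, among them the genes named next. Esrp1, an epithelial splicing regulator, was 10.8-fold higher, the adhesion gene Epcam 4.30-fold, the tight junction gene Cldn7 3.81-fold and the cadherin gene Cdh1 3.59-fold. Pax8 (11.54 against 11.52) and Krt8 (log2 difference 0.21) did not pass. The list had a median log2 difference of 1.21 and adjusted p = 4.92e-12 (adjusted p = 0.266 with an estimated correlation).

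Among 18 genes of the ureteric trunk and collecting duct, 7 were higher, 2 lower and 9 not passing (9 higher and 2 lower when adjusted over the list alone). Of the 7 higher, 1 passed without each array in turn, Wnt7b. This gene of a Wnt ligand of the ureteric trunk was 11.7-fold higher at 8.47 against 4.92. Aqp2, the vasopressin-regulated water channel, was 2.59-fold higher and the sodium channel gene Scnn1b 2.34-fold higher. The list had adjusted p = 0.00643 (adjusted p = 0.534 with an estimated correlation) and did not pass without the GFP-high array of kidney A (adjusted p = 0.106). Without the GFP-negative array of kidney B or D, Aqp2 had adjusted p = 0.0845 or 0.0617, and Scnn1b did not pass with any 1 of the 4 arrays left out (adjusted p 0.0527 to 0.12).

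The ureteric bud tip list had 4 of 13 members higher, 0 lower and 9 not passing (4 higher when adjusted over the list alone), and did not pass (adjusted p = 0.468). Wnt11 was 2.08-fold, Moxd1 2.06-fold, Gfra1 1.98-fold and Etv5 1.94-fold higher, and Ret, the receptor that defines the tip, was at 4.57 against 4.88 and did not pass. With 1 array left out, Wnt11 ranged in log2 difference from 0.716 to 1.403 and Etv5 from 0.727 to 1.18. Moxd1 ranged from 0.843 to 1.236 and Gfra1 from 0.904 to 1.065. These fits leave 1 residual degree of freedom, so calls are lost more easily. Without the GFP-high array of kidney A, adjusted p was 0.077, 0.118, 0.0535 and 0.123 for Wnt11, Moxd1, Gfra1 and Etv5, and without that of kidney B it was 0.0266, 0.0948, 0.0577 and 0.0536. Without the GFP-negative array of kidney B it was 0.188, 0.0223, 0.0302 and 0.0907, and without that of kidney D 0.159, 0.0504, 0.0424 and 0.151. Wnt11 had 0.0509 when all probe sets were tested. In the urothelium list of 9 genes, Upk1a was 7.10-fold higher and Upk1b lower at 4.04 against 4.87 (adjusted p = 0.0465 without the GFP-high array of kidney A and 0.082, 0.121 and 0.0933 without that of kidney B and the GFP-negative arrays of kidneys B and D), and 7 did not pass (1 higher and 2 lower when adjusted over the list alone). That list did not pass (adjusted p = 0.581), with a mean difference of 0.114 against a median of -0.263 and a downward direction in the test.

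**Figure D2:**
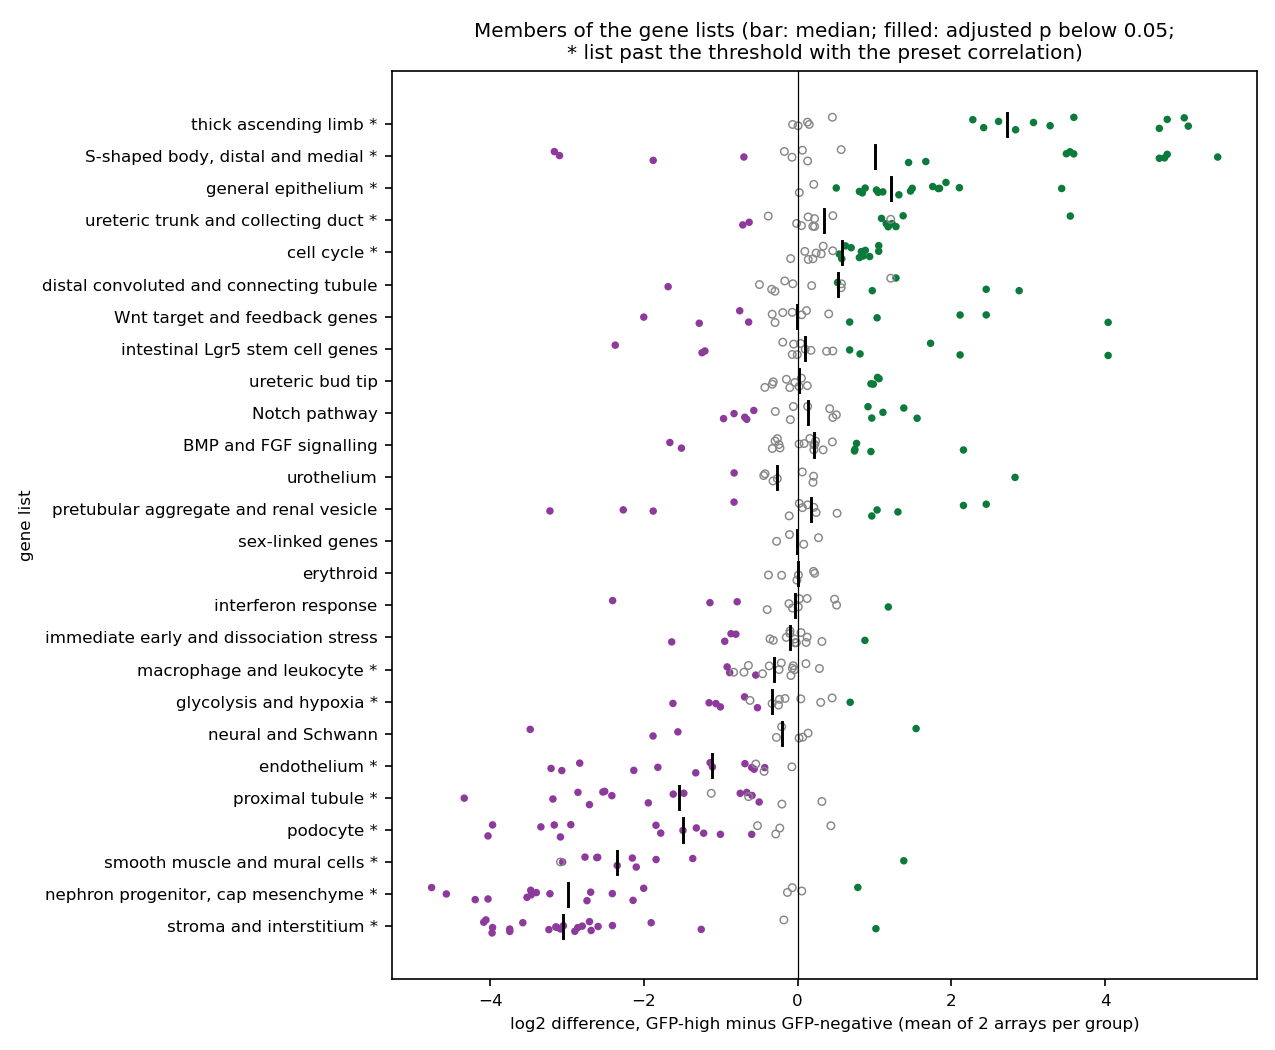
Log2 difference between GFP-high and GFP-negative cells (horizontal axis, difference of means over 2 arrays per group) of every measured member of the 26 gene lists (vertical axis), with filled points for adjusted p below 0.05, open points for other genes, a bar at each list's median and an asterisk at lists that passed with the preset correlation. The thick ascending limb median lies at 2.73 and the stroma median at -3.05.

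Nephron progenitor genes were lower in GFP-high cells, with 14 of 18 members of the cap mesenchyme list lower, 1 higher and 3 not passing (14 lower and 1 higher when adjusted over the list alone). All 14 lower members passed without each array in turn. Beside Six2, Itga8 and Osr1, Wt1, a zinc finger transcription factor also of podocytes, was 16.3-fold lower at 6.68 ± 0.83 against 10.70 ± 0.21 (SD, n = 2 each). Uncx, a homeobox gene, was higher at 11.16 against 10.38, with adjusted p = 0.134 and 0.0994 without the GFP-high arrays of kidneys A and B and 0.0982 without the GFP-negative array of kidney B. Sall1 (9.30 against 9.25), Hoxa11 and Hoxd11 did not pass. The median log2 difference was -2.98 with adjusted p = 1.5e-14 (adjusted p = 0.343 with an estimated correlation). Stromal genes showed the largest median shift of the 26 lists in the main fit, though not under every alternative. Of 23, 21 were lower, 1 higher and 1 not passing (21 lower and 1 higher when adjusted over the list alone). Of the 21, 18 passed without each array in turn. Postn, which encodes the matrix protein periostin, was 15.7-fold lower, and so was Tcf21, a transcription factor of stroma and podocytes. Ntn1, a guidance cue, was the higher member at 8.33 against 7.31, with adjusted p = 0.14 and 0.201 without the GFP-high arrays of kidneys A and B and 0.132 without the GFP-negative array of kidney B. The stroma list had a median log2 difference of -3.05 and adjusted p = 7.54e-22 (adjusted p = 0.343 with an estimated correlation).

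The list of pretubular aggregate and renal vesicle genes was split, with 5 of 16 higher, 4 lower and 7 not passing (6 higher and 4 lower when adjusted over the list alone), and did not pass (adjusted p = 0.502). Of the 5 higher ones 3 passed, and of the 4 lower ones 2 passed, without each array in turn, among them the 4 genes named next. Dkk1, a secreted Wnt antagonist, was 5.48-fold higher and Fgf8, a growth factor of nascent nephrons, 4.46-fold higher. Bmper, a BMP-binding protein gene, was 4.82-fold lower, and Tmem100 was lower at 4.07, below the background level of 4.24, against 7.29. Lhx1, at 8.73 against 8.66, did not pass.

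Wnt target and feedback genes went both ways, with 5 of 16 higher, 4 lower and 7 not passing (5 higher and 4 lower when adjusted over the list alone). Lgr5, which the sort itself selects, Dkk1, Rnf43 (4.33-fold), Ccnd1 and Znrf3 were higher, of which Rnf43 and Znrf3 encode ubiquitin ligases that remove Wnt receptors. Nkd1, a feedback inhibitor, was lower at 7.50 against 9.50, with Apcdd1, Notum and Kremen1 also lower. With any 1 of the 4 arrays left out Znrf3 (adjusted p 0.0729 to 0.113), Notum (0.0601 to 0.168) and Kremen1 (0.0777 to 0.236) did not pass, nor did Apcdd1 without the GFP-high array of kidney A (0.087) or B (0.0798). Axin2, a widely used Wnt target, was at 6.63 against 6.82 and did not pass. The list did not pass (adjusted p = 0.65), with a mean difference of 0.333, a median of -0.008 and an upward direction in the test. Of 17 genes that mark intestinal Lgr5 stem cells, 5 were higher (1 of them Lgr5, which the sort itself selects), 3 lower and 9 not passing (6 higher and 3 lower when adjusted over the list alone). Of the 5 higher ones 3 passed, and of the 3 lower ones 2 passed, without each array in turn. Prom1, which encodes a membrane glycoprotein, was 3.32-fold higher, although a second probe set of this gene had a log2 difference of -0.058, and Smoc2, a matricellular protein gene, was 5.18-fold lower. Ascl2, the intestinal stem cell transcription factor, was at 3.88 against 3.85, within background. That list did not pass either (adjusted p = 0.359).

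In the Notch pathway 5 of 17 members were higher, 5 lower and 7 not passing (7 higher and 5 lower when adjusted over the list alone), and the list did not pass (adjusted p = 0.489). The target gene Hes5 was 2.94-fold, the receptor gene Notch3 2.60-fold, Hes1 2.16-fold and the ligand gene Jag1 1.95-fold higher, with Hey2 also higher, while Notch2, Dll4, Lfng, Hey1 and Heyl were lower. Hes5 alone passed without each array in turn. With any 1 of the 4 arrays left out Notch2 (adjusted p 0.0761 to 0.14), Lfng (0.06 to 0.232), Hey1 (0.0606 to 0.278) and Heyl (0.091 to 0.205) did not pass. Without the GFP-high array of kidney A, adjusted p was 0.0909 for Notch3, 0.0581 for Hes1, 0.059 for Jag1, 0.14 for Dll4 and 0.151 for Hey2. Without that of kidney B it was 0.0663 for Notch3, 0.0909 for Hes1, 0.21 for Dll4 and 0.132 for Hey2. Hey2 had 0.074 without the GFP-negative array of kidney B, and Hes1 had 0.081 and Dll4 0.151 without that of kidney D. Of 21 genes of BMP and FGF signalling, 5 were higher, 2 lower and 14 not passing (5 higher and 2 lower when adjusted over the list alone), and the list did not pass (adjusted p = 0.468). Beside Fgf8, Bmp7, Id4, Etv5 and Smad7 were higher, and none of these 4 passed with any 1 of the arrays left out (adjusted p 0.0547 to 0.0965 for Bmp7, 0.0949 to 0.226 for Id4, 0.0536 to 0.151 for Etv5 and 0.0596 to 0.0795 for Smad7). In the other direction the feedback inhibitor gene Spry4 was 3.16-fold and the progenitor growth factor gene Fgf20 2.85-fold lower, to a GFP-high value of 3.56 that lies below the background level of 4.24.

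Proximal tubule genes were lower in GFP-high cells, with 14 of 18 lower, 0 higher and 4 not passing (15 lower when adjusted over the list alone). Of the 14, 5 passed without each array in turn, among them the 4 genes named next. Beside Slc34a1, Keg1 was 9.08-fold lower, Lrp2, the endocytic receptor megalin, 7.25-fold lower at 6.44 against 9.30, and Slc27a2, a fatty acid transporter gene, 6.53-fold lower. The median log2 difference was -1.55 with adjusted p = 1.08e-10 (adjusted p = 0.429 with an estimated correlation). In the podocyte list 13 of 17 were lower, 0 higher and 4 not passing (13 lower and 1 higher when adjusted over the list alone), with adjusted p = 2.24e-09 (adjusted p = 0.407 with an estimated correlation). It shares Wt1 and Tcf21 with the lists above, and 4 of the 13 passed without each array in turn. Ptpro, a podocyte phosphatase gene, was 10.1-fold lower, with adjusted p = 0.125 without the GFP-high array of kidney A, 0.0702 without that of kidney B and 0.0543 without the GFP-negative array of kidney B. Podxl, which encodes the sialomucin podocalyxin, was 8.97-fold lower. Its log2 difference was -2.377 without the GFP-high array of kidney A and -3.954 without that of kidney B. Without the GFP-negative arrays of kidneys B and D it was -2.678 and -3.654. The call of Podxl was lost in all of these fits but that without the GFP-high array of kidney B. Podocyte genes averaged 0.458 higher on the log2 scale in the kidney B array than in the kidney A array of GFP-high cells, and 0.548 higher in kidney B than in kidney D among GFP-negative cells.

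In the smooth muscle and mural cell list 9 of 11 were lower, 1 higher and 1 not passing (10 lower and 1 higher when adjusted over the list alone). None of these members passed without each array in turn, while the list did (adjusted p 8.12e-07 to 0.000396). It had a median log2 difference of -2.35 and adjusted p = 1.41e-05 (adjusted p = 0.407 with an estimated correlation). The contractile genes Myh11, Acta2, Actg2 and Tagln were 8.32-fold, 6.80-fold, 6.12-fold and 6.07-fold lower, and Notch3 was the higher member (adjusted p = 0.0909 and 0.0663 without the GFP-high arrays of kidneys A and B). The contractile genes varied between arrays of a group, with Myh11 at 8.27 ± 1.81 in GFP-negative cells (SD, n = 2). With 1 array left out, log2 differences ran from -4.334 to -1.78 for Myh11 and -3.629 to -1.903 for Acta2. For Actg2 they ran from -3.862 to -1.363 and for Tagln from -3.3 to -1.902. Muscle genes averaged 0.711 higher in kidney B than in kidney A among GFP-high cells and 1.05 higher in kidney B than in kidney D among GFP-negative cells. Without the GFP-high array of kidney A, adjusted p was 0.327, 0.105, 0.394 and 0.212 for Myh11, Acta2, Actg2 and Tagln, and without that of kidney B it was 0.209, 0.0359, 0.238 and 0.103. Without the GFP-negative array of kidney B it was 0.0938, 0.185, 0.185 and 0.122, with a log2 difference of -1.78 for Myh11 and -1.36 for Actg2. Without the GFP-negative array of kidney D it was 0.014, 0.0999, 0.0193 and 0.0352. When all probe sets were tested Myh11 had 0.0848 and Actg2 0.124, and Actg2 had 0.0769 with robust variance.

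Of 15 endothelial genes 12 were lower, 0 higher and 3 not passing (14 lower when adjusted over the list alone), with adjusted p = 5.57e-10 (adjusted p = 0.407 with an estimated correlation). Of the 12, 4 passed without each array in turn, and these are named next. Emcn was 9.23-fold, Cldn5 8.38-fold, Cdh5, the endothelial cadherin gene, 7.13-fold and Eng 4.38-fold lower. In the macrophage and leukocyte list 3 of 16 were lower and 13 did not pass (3 lower when adjusted over the list alone). These were Mrc1, Laptm5 and Cd68, at 7.56 against 8.11 for Cd68. The list had adjusted p = 0.0196 (adjusted p = 0.534 with an estimated correlation), and did not pass without the GFP-high array of kidney A (adjusted p = 0.112) or the GFP-negative array of kidney D (adjusted p = 0.109), nor with genes below the 25th percentile of level left out (adjusted p = 0.0734). Without the GFP-high arrays of kidneys A and B and the GFP-negative arrays of kidneys B and D in turn, adjusted p was 0.119, 0.119, 0.0274 and 0.0662 for Mrc1, 0.258, 0.117, 0.0736 and 0.224 for Laptm5, and 0.187, 0.0811, 0.241 and 0.168 for Cd68. When all probe sets were tested Laptm5 had 0.0715 and Cd68 0.0789, and Cd68 had 0.0517 with each array centred on its median. None of 6 erythroid genes passed (0 when adjusted over the list alone), with Epb42 at 3.77 against 4.15 and Hbb-y at 3.74 against 3.52, below the background level in both groups (Epb42 passed after cyclic loess normalization, adjusted p = 0.0462), and the list had adjusted p = 0.797 (median 0.001, mean -0.026, downward in the test).

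In the neural and Schwann list 3 of 9 were lower, 1 higher and 5 not passing (3 lower and 1 higher when adjusted over the list alone), and the list did not pass (adjusted p = 0.11). Ngfr, the low-affinity neurotrophin receptor gene, was 11.2-fold lower, Elavl4 3.68-fold lower (its GFP-high value of 3.94 lies below the background level of 4.24) and Fabp7 2.94-fold lower, and the receptor tyrosine kinase gene Erbb3 was 2.91-fold higher. Fabp7 had adjusted p = 0.111 and 0.0599 without the GFP-high arrays of kidneys A and B and 0.0707 without the GFP-negative array of kidney D. Sox10, the marker of neural crest and Schwann cells, was at 4.37 against 4.23 and did not pass.

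Of 19 cell cycle genes 11 were higher in GFP-high cells, 0 lower and 8 not passing (12 higher when adjusted over the list alone). Cenpf and Bub1 were each 2.08-fold, Aurka 1.91-fold and Kif11 1.84-fold higher. A second probe set of Kif11 had a log2 difference of 0.703 and did not pass when all probe sets were tested (limma adjusted p = 0.0662). Pcna (11.37 against 11.28), Mki67 (10.02 against 9.56), Ccnb2, Birc5, Mcm2, Mcm3, Mcm5 and Mcm6 did not pass. The list had a median log2 difference of 0.574 and adjusted p = 8.64e-06 (adjusted p = 0.407 with an estimated correlation), and passed without each of the 4 arrays in turn (adjusted p 1.04e-06 to 7.65e-05). No single member passed without each array in turn. Without the GFP-high arrays of kidneys A and B and the GFP-negative arrays of kidneys B and D in turn, adjusted p was 0.241, 0.18, 0.0894 and 0.0186 for Cenpf, 0.0962, 0.0559, 0.0816 and 0.0428 for Bub1, and 0.164, 0.135, 0.0844 and 0.0268 for Kif11, while Aurka had 0.0601 without the GFP-high array of kidney A and Cenpf 0.056 when all probe sets were tested.

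Of 15 glycolysis and hypoxia genes 6 were lower, 1 higher and 8 not passing (6 lower and 1 higher when adjusted over the list alone). Ndrg1 was 3.08-fold, P4ha1, a collagen prolyl hydroxylase gene, 2.22-fold, Adm 2.09-fold and Vegfa 2.01-fold lower, and the higher member was Pfkp, which did not pass with any 1 of the 4 arrays left out (adjusted p 0.0696 to 0.0961). The list had adjusted p = 0.0165 (adjusted p = 0.544 with an estimated correlation) and did not pass without the GFP-high array of kidney B (adjusted p = 0.0847) or the GFP-negative array of kidney D (adjusted p = 0.232), nor with genes below the 25th percentile of level left out (adjusted p = 0.0734). Without the GFP-high arrays of kidneys A and B and the GFP-negative arrays of kidneys B and D in turn, adjusted p was 0.125, 0.194, 0.0413 and 0.13 for P4ha1, 0.0284, 0.0616, 0.156 and 0.15 for Adm, and 0.0761, 0.0784, 0.0255 and 0.0451 for Vegfa.

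The immediate early genes Fos (11.11 against 11.21), Jun (11.77 against 11.46) and Egr1 (11.28 against 11.43) were bright in both groups and did not pass. In that list of 17, which includes genes induced by dissociation, 4 were lower, 1 higher and 12 not passing (4 lower and 1 higher when adjusted over the list alone). Socs3, a cytokine feedback inhibitor gene, was 3.11-fold, Ier3 1.93-fold and Nr4a1 1.82-fold lower, and Klf6 was 1.83-fold higher. A second probe set of Socs3 had a log2 difference of -0.6 and did not pass when all probe sets were tested (limma adjusted p = 0.0576). Junb was also lower, with log2 differences of -1.048 to -0.558 with 1 array left out, and lost its call in each of these fits. The list had adjusted p = 0.11, and 0.0229 without the GFP-high array of kidney A. Without the GFP-high arrays of kidneys A and B and the GFP-negative arrays of kidneys B and D in turn, adjusted p was 0.19, 0.104, 0.136 and 0.0473 for Ier3, 0.134, 0.187, 0.0463 and 0.136 for Nr4a1, and 0.169, 0.166, 0.0908 and 0.0258 for Klf6.

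Of 12 interferon response genes 3 were lower, 1 higher and 8 not passing (3 lower and 2 higher when adjusted over the list alone), and the list did not pass (adjusted p = 0.411). The chemokine gene Cxcl10 was 5.30-fold lower and Usp18 2.20-fold lower. Ifit1 was lower at 3.43 against 4.22, both below the background level, with adjusted p 0.0531 to 0.0752 without 1 array, and Ifit3 was 2.27-fold higher. Ifit3 had adjusted p = 0.053 without the GFP-high array of kidney B and 0.148 and 0.14 without the GFP-negative arrays of kidneys B and D. No sex-linked gene passed (0 of 4 when adjusted over the list alone) and the list had adjusted p = 0.827. Xist, expressed in female cells, stood at 10.33 against 10.60, and the Y-linked genes Eif2s3y, Kdm5d and Uty stood at 7.71 against 7.82, 7.28 against 7.20 and 7.19 against 6.92.

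None of the 13 lists that passed with the preset correlation passed with an estimated correlation after adjustment, where 3 had an unadjusted p below 0.05. That version has only 2 degrees of freedom, so its failures do not show that correlation between genes undid a shift. Fry, which asks only whether a list's genes move on balance in a single direction, called 11 of the 26. The podocyte (fry adjusted p = 0.0557), proximal tubule (0.0502), smooth muscle (0.071), ureteric trunk (0.071), macrophage (0.153) and glycolysis (0.172) lists failed it. The Wnt target (0.0164), intestinal (0.0215), urothelium (0.00449) and neural (0.00486) lists passed it but not camera. Both the Wnt target and the intestinal list include Lgr5, which the sort itself selects. They were not tested without it, so their fry results cannot be read as a shift of the other members. The differences could be compared between 2 sets of arrays that share none, GFP-high against GFP-negative within kidney B and GFP-high of kidney A against GFP-negative of kidney D. Across genes, which are not independent replicates, they had Pearson's r of 0.894 and Spearman's rho of 0.664, and 71.5% of the 18820 genes had the same sign in both, where 49.9% would if the signs were independent. Lgr5 differed by 3.96 on the log2 scale within kidney B and by 4.12 in the other set, and Umod by 4.37 and 5.69. Correlation between arrays over genes was 0.995 within each group and 0.956 to 0.962 between groups. The values of the 2 groups did not overlap for 10778 genes (57.3%), where chance gives 33.3% for 2 against 2.

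**Figure D3:**
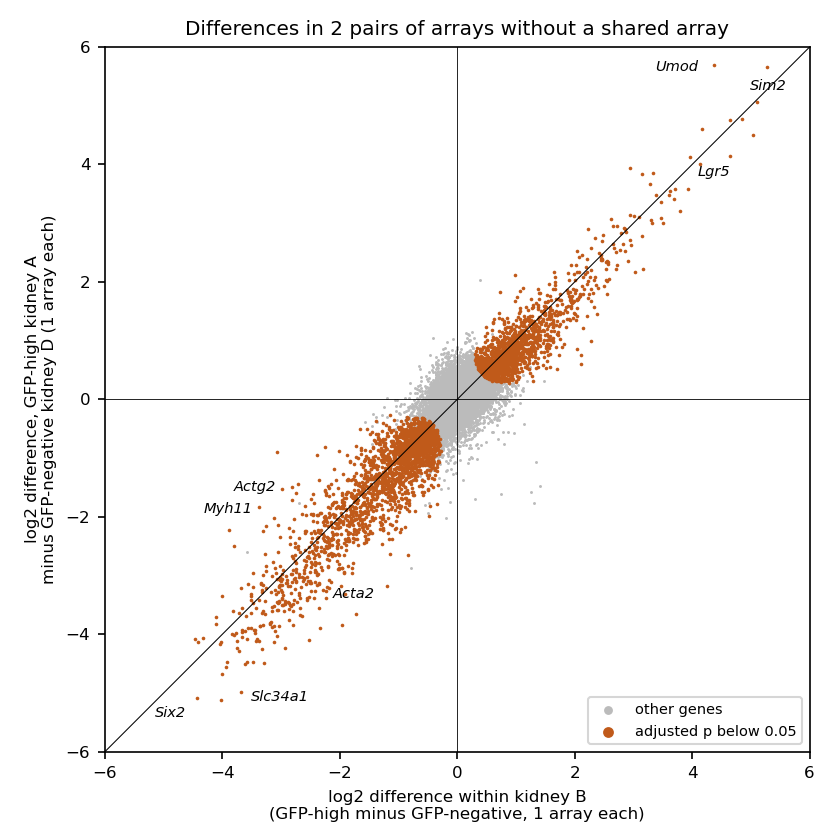
Log2 difference between GFP-high and GFP-negative cells within kidney B (horizontal axis) against the difference between GFP-high of kidney A and GFP-negative of kidney D (vertical axis), 1 point per gene, with genes of adjusted p below 0.05 in orange and the line of equality. Pearson's r across genes is 0.894, and the muscle genes Myh11 and Actg2 lie farther from 0 in kidney B than in the other set, while Acta2 lies nearer to 0.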

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

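The test over all probe sets was planned, while the use of proximal tubule genes against autofluorescence was chosen after the results were seen. Among probe sets outside the gene test, 795 of 12457 without a gene name here passed the threshold, 438 higher and 357 lower in GFP-high cells, when all probe sets were tested together. Of 1881 probe sets that name several genes, 251 passed in the same test. Both were singled out because a signal appears in data that the comparison of genes does not use. Over all 35556 probe sets 3970 passed. That is a larger share than among the unnamed ones, and a somewhat smaller share than among those that name several genes.

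Of 16 thick ascending limb genes 11 were higher in the GFP-high fraction and 5 did not pass (adjusted p = 4.92e-12 for the list, adjusted p = 0.266 with an estimated correlation). Autofluorescence of differentiated tubules caught in the gate would raise proximal tubule genes too. Their median log2 difference was -1.549 (standard error of the mean over genes 0.291), and 1 of 18 was higher in both sets of arrays. These genes are not independent replicates, with an estimated correlation of 0.645, so that error is likely too small. The list's mean was -1.354 within kidney B and -1.949 in the other set of arrays. This direction argues against autofluorescence as the whole cause. A hypothesis that stays open is that the reporter cells include cells of the distal nephron. Its test is whether Lgr5 and the segment genes lie in the same cells, which bulk RNA cannot show.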

How the results depend on the processing

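All alternatives except the values within kidney B were set before the data were examined. No gene among the 3620 calls changed sign in any fit by gene. The block and variance settings leave each difference as it was, so they could not change a sign. The calls also come from the same 4 arrays, so this is weak evidence of stability. Without 1 array, which leaves 1 residual degree of freedom, the calls ranged from 1123 to 1749, the higher ones from 387 to 603 and the lower ones from 729 to 1148. Of 94 named genes that passed, 61 passed without each of the 4 arrays and 33 lost the call without at least 1. Leaving out genes below the median level gave 2385 calls, 1192 of them lower, from 9410 genes tested, and all 2244 of the main calls still tested were kept. Asking also for a 2-fold difference gave 1651 calls. The array number as a replicate block gave 2959 calls and changed the count by less than 1.5 times, and Actg2 (adjusted p = 0.0607) and Cd68 (adjusted p = 0.0734) did not pass with it. Deviations from the group means correlated weakly across genes, at -0.198 for arrays with the same number and 0.198 for those with the same kidney letter, which with 2 arrays per group is the same value with its sign turned. The crossed replicate block, which joins the kidney B arrays, gave 4102 calls. Normalization gave 3844 (quantile), 4011 (median centring) and 3743 calls (cyclic loess), with 45.6%, 52.9% and 36.7% of them higher against 42% in the values as deposited.

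Of the 26 lists, 0 passed camera with an estimated correlation, where 3 had an unadjusted p below 0.05, and 24 changed in either direction by fry's mixed test. The estimated version has only 2 degrees of freedom. The thick ascending limb list had an estimated correlation of -0.026, below the preset 0.01, yet its camera p rose from 7.3e-13 to 0.0165. In the other lists that passed, the estimate was above the preset. It ran from 0.016 (general epithelium) to 0.645 (proximal tubule), with 0.431 for podocyte genes. If these estimates hold, the p-values that camera gave with the preset correlation are too small for those lists. The macrophage list and the glycolysis list each had adjusted p = 0.0734 with genes below the 25th percentile of level left out, and the distal convoluted and connecting tubule list passed with those below the median left out (adjusted p = 0.0263). The cause of these shifts was not tested. With all probe sets, many of them dim, the correlation of the 2 sets of arrays was 0.783 in place of 0.894. It was 0.916 with genes below the 25th percentile of level left out and 0.942 with those below the median left out. Agreement was thus lower where more dim features were included, and the cause was not tested further. Lgr5 differed by 3.957 within kidney B, a value of 1 array per group chosen after seeing the data. The kidney letter as a random block could not be estimated from 4 arrays and was not run, a pseudocount does not apply to values that are already log2, and list shifts were not run over all probe sets. The agreement of the 2 sets of arrays gives no value without 1 array or under a block or another variance model.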

Other observations

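The tests and gene groups in this part were chosen after the results were seen. Of 42 collagen genes, which include Col1a1, Col1a2, Col3a1 and Col5a2 of the stroma list and 2 of the podocyte list, 16 were lower, 1 higher and 25 not passing (adjusted p = 1.46e-07 over 20 families, adjusted p = 0.411 with an estimated correlation), among them Col6a3 at 5.14 against 8.79 and Col26a1 at 5.89 against 9.13. Of 18 ADAMTS protease genes 8 were lower, 1 higher and 9 not passing (adjusted p = 0.000647, adjusted p = 0.519 with an estimated correlation). Of 10 laminin genes 3 were higher, 2 lower and 5 not passing, with the family not passing (adjusted p = 0.887). Lama4 (5.53 against 9.36) and Lama2 (4.62 against 8.09) were lower, and Lama1 (11.32 against 9.41), Lamb1 and Lamc1 higher. Without the GFP-high array of kidney A, adjusted p was 0.0535 for Lama1 and 0.063 for Lamb1, and without that of kidney B 0.0717 for Lamc1. Without the GFP-negative arrays of kidneys B and D it was 0.0574 and 0.0512 for Lamb1 and 0.0904 and 0.0709 for Lamc1. Of 23 claudin genes 9 were higher and 4 lower, with the family not passing (adjusted p = 0.0967), where Cldn19 and Cldn16 were higher and Cldn2, of the proximal tubule, was lower at 4.64 against 6.96. Of 36 Hox genes 12 were higher, 8 lower and 16 not passing, with the family not passing (adjusted p = 0.696), and the largest differences were in Hoxc8 (6.55 against 9.15), Hoxd8 (10.01 against 7.60) and Hoxd12 (3.96, below the background level, against 6.27). Counts of collagens, ADAMTS genes and claudins kept these directions under quantile, median and cyclic loess normalization, with 15 to 18 collagens lower. The laminin family's median log2 difference turned from 0.013 to -0.034 under cyclic loess normalization, while 3 genes were higher and 2 lower either way.

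Among genes on none of the fixed lists, the calcium-sensing receptor gene Casr stood at 7.80 against 4.32 (log2 difference 3.47, SE 0.139, limma adjusted p = 1.665e-05) and Mal at 9.10 against 6.31. Of 10 genes listed for the macula densa, the sensor patch at the end of the thick ascending limb, 9 were measured, 2 were higher (Slc12a1 and Pappa2), 2 lower (Robo2 and Avpr1a) and 5 did not pass. Avpr1a had adjusted p = 0.0616 without the GFP-high array of kidney B and 0.0966 and 0.0947 without the GFP-negative arrays of kidneys B and D. Pappa2 was higher, with a GFP-high value of 7.69 ± 0.54 (SD, n = 2) against a GFP-negative value below the background level of 4.24, while Nos1 was at 5.06 against 4.75 and Ptgs2 at 8.70 against 8.68. Among genes of the R-spondin system, Lgr4 was higher at 11.04 against 10.48 (adjusted p 0.0997 to 0.176 without 1 array), Lgr6 lower at 4.44 against 5.81, and the ligand genes Rspo3 and Rspo1 lower at 4.37 against 7.47 and 7.66 against 8.98.

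Smooth muscle and podocyte genes were higher in kidney B than in the other array of the same fraction, by a mean of 0.711 and 0.458 among GFP-high and 1.05 and 0.548 among GFP-negative arrays, with 8 of 11 muscle and 13 of 17 podocyte genes higher in both fractions. A uniform shift of whole arrays is argued against, since the median difference over all genes was at most 0.024. This median does not test a shift that depends on level. Carry-over of GFP-negative cells into the kidney B GFP-high sort cannot raise a GFP-negative array, and for the GFP-high arrays alone it stays open. The added signal was 5.43% of the kidney B GFP-negative signal in the median of 28 muscle and podocyte genes (bootstrap 95% interval 2.75 to 7.57) and 1.25% in that of 82 genes of the stroma, cap mesenchyme, proximal tubule, endothelium and macrophage lists (0.0849 to 2.79), and the intervals overlap. Overlap is no test of the difference, and the intervals resample genes, which are not independent replicates. The muscle and podocyte lists were also singled out for being higher in kidney B, so these values cannot decide. This test replaced an earlier one after its value was seen, because the earlier one chose its genes by fold, and no biological explanation was tested.

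Lgr5 in GFP-negative cells, at 6.31 or more, lay above 4.64, the 99th percentile of olfactory receptor genes on those arrays. That percentile does not give the background of the Lgr5 probe set itself. The GFP-negative value was 6.08% of the GFP-high signal of Lgr5. Carry-over of GFP-high cells would leave every abundant transcript of those cells at no less than the share of Lgr5, and as the whole cause it is argued against, if array signals are proportional to RNA. Of 361 other genes of the fixed lists 6 had a larger log2 difference than Lgr5, 2 of them with Holm adjusted p below 0.05 (Sim2, at 2.27%, and Slc12a1, at 2.95%) and 3 with Benjamini-Hochberg adjustment (one-sided limma tests). Cells that express Lgr5 without detectable reporter, and cross-hybridisation of the Lgr5 probe set, stay open and were not tested. This count replaced 3 earlier ones after their values were seen (8 of the other 11 largest increases, 6 genes by 95% intervals and 6 by a two-sided adjustment), because these did not guard against choosing genes by fold, and the bound was lowered from 3 genes to 1 after the 2 were seen, because the explanation allows none.

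Olfactory receptor genes had a median log2 difference of 0.177 against 0.051 for all genes, with 35 of 990 higher and 1 lower (adjusted p = 9.04e-07, adjusted p = 0.707 with an estimated correlation). Without 1 array 0 to 3 were higher, and 34 were after quantile, 98 after median and 22 after cyclic loess normalization, with medians of 0.151, 0.273 and 0.127. Medians of other receptor and hair gene families were 0.136 (vomeronasal receptors), 0.137 (taste receptors) and 0.19 (keratin-associated proteins). The excess over all genes was 0.105 after quantile and 0.127 after cyclic loess normalization, and level-matched lists of other genes had a median of 0.06, the highest of 1000 being 0.075. Of 6043 genes with a mean below 4.24, 103 were called higher and 170 lower.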
